A study of Arabidopsis thaliana with 8 samples.

How the data were processed

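Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on nuclei of a single cell type, the non-hair cells of the Arabidopsis thaliana root epidermis. Per the labels' protocols, the nuclei were tagged with biotin under a promoter active in non-hair cells and purified by affinity (the INTACT method) from roots of plants of the Col-0 accession aged 10 days. The antibodies were directed against H3 monomethylated at lysine 4 (H3K4me1), H3 trimethylated at lysine 4 (H3K4me3), H3 acetylated at lysine 27 (H3K27ac), H3 trimethylated at lysine 27 (H3K27me3), the histone variant H2A.Z, and histone H3 itself. Each of these 6 targets had 1 library. The other 2 of the 8 samples were input chromatin, one of them named as the input for H3K27me3, and no values of the inputs were analysed here. The H3K27me3 library had an input of its own, so a difference between that library and the others in preparation could not be separated from the mark.

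The deposited files listed the called regions of each library as chromosome, start and end, and gave no score, height, read count or p-value, so the unit of every value is base pairs or a count of regions made by the authors' caller. Per the submitters' processing notes, Bowtie2, SAMtools 0.1.19, deepTools 2.0 and HOMER had been used with genome build TAIR10; the caller's settings, its threshold and the control library it used are not given in the sources used here. The names of the deposited files describe HOMER regions that had been sorted and merged. The sequencing depth of every library is unknown here, and a deeper library can yield more and longer regions, so numbers of regions and covered bases are not measures of the amount of a mark. In every library a large group of regions shared 1 smallest size, from 179 bp for H3K27ac to 254 bp for H3K4me1. Smallest sizes of H3K4me3, H3K27ac and H2A.Z lay under 200 bp and those of H3K4me1, H3K27me3 and H3 above it, which matters for any threshold of 200 bp: 1 region of the smallest size could mark a gene for the second group and not for the first.

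Regions on chromosomes 1 to 5 were used. Mitochondrial regions were left out; there was 1 for H3K4me3, 2 for H3K27me3 and 4 for H3. Genes were taken from the RefSeq annotation of TAIR10.1, whose nuclear chromosomes carry the TAIR10 coordinates; all region ends lay within their lengths. The annotation held 37899 nuclear genes, of which 27444 were protein-coding. Annotated ends of genes were used, since the starts of transcription in these cells were not measured. Each region was placed by its midpoint. A 5' zone reached 500 bp on either side of the start of a protein-coding gene and took precedence over a 3' zone of the same width at the gene's end, which took precedence over the remaining gene body; intergenic sequence was called proximal within 1000 bp of any gene and distal beyond that. Flanks of centromeres reached 3 Mb to either side of centres set by hand to rounded positions, at 15, 4, 14, 4 and 12 Mb on chromosomes 1 to 5, so shares near centromeres and results without them are approximate. Distal space made up 11.0% of the 119 Mb of nuclear sequence.

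The observed value of each statistic was compared with 1000 circular shifts of a mark's regions along their chromosomes, which keep the lengths and spacing of regions and break their relation to genes and to other marks. A value was called higher or lower when it lay outside the range of all 1000 shifts. Shifts describe these libraries, and with 1 library per mark no difference has a replicate check. For sharing of bases, the first mark of the pair was shifted against the second. The log2 ratio is that of the observed shared bases to the mean of the shifts. Coverage around gene starts was taken in 500 bp windows on each side of the start, for protein-coding genes of at least 1000 bp with no gene in the 1000 bp upstream (isolated starts), and separately for starts with an oppositely oriented gene starting 200 to 1000 bp upstream (divergent starts). A gene was called marked when at least 200 bp of it were covered. Shares of regions carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

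10 gene lists with 156 measured members were fixed before the data were examined: non-hair fate regulators, root hair genes, endodermis markers, stele, xylem and phloem markers, root cap and root tip markers, shoot and floral developmental regulators, embryo and seed genes, photosynthesis genes, housekeeping genes, and genes of root nutrient and water transport. Members were matched by locus, and 4 whose symbol and locus disagreed were left out (SGN3, TIP41L, SAND and EF1A). The share of marked members was given its percentile among 10000 random lists of the same size and the same spread over 10 classes of gene length. Random lists with an equal number of marked members were split evenly above and below. A list was said to stand apart when its percentile lay in the outer 2.5% on either side. This bound was set after the data had been seen. About 5% of the 60 comparisons of a list with a mark would pass it by chance. With ties counted in full, more than 2.5% of random lists were as extreme for some calls near the bound. On root hair genes these were H3K27me3 (361 of 10000), H3K4me1 (302) and H3K4me3 (267). The others were H2A.Z on shoot and floral regulators (326) and H3K4me3 on root cap and root tip markers (330).

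Named genes followed a rule fixed before the data were examined. Up to 10 non-hair regulators and 10 root hair genes were named in list order, and for other lists the 2 to 4 members with the most bases of the mark in question. Beyond the lists, the rule took the 2 longest regions of each mark, the 5 longest distal regions with H3K27ac and H3K4me1 and without H3K4me3, and the 5 genes with the most bases covered by both H3K4me3 and H3K27me3. The tests of the main comparisons and their alternatives were also fixed before the data were examined. Added afterwards were the bound above, shifts of only 20 to 200 kb, the exclusion of regions at the smallest size, and, among the additional observations, the tests of distal H3K27ac regions, the gene classes and the gene families. The shift statistics were tested on simulated data: 20 pairs of random sets of 20000 regions gave 1 call over 4 statistics, in the distal share, and 20 pairs in which 10% of the regions had been planted at gene starts or on the partner's regions were called in all 20 for each statistic, with 200 shifts per simulation. The random regions were placed uniformly along the chromosomes, so the simulation did not show how often clustered regions would be called. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are given 1-based.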

Results

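The data consisted of called regions for 5 chromatin marks and for histone H3 in non-hair cells of the Arabidopsis root epidermis, with 1 library each. In animal genomes, H3K4me1 together with H3K27ac and without H3K4me3 is a usual signature of enhancers away from gene starts. The placement of these marks across a plant genome in a single cell type was compared here. H3K4me3 and H3K27ac are otherwise known from starts of active genes, H3K27me3 from genes silenced by Polycomb proteins, and H2A.Z is a variant of histone H2A found near gene starts and across some silent genes. There were no replicates, and the depth of the libraries is unknown, so every comparison describes these libraries.

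H3K27ac had the most regions, 36146, and covered 9.07% of the nuclear genome. H3K4me1 covered the most sequence, 12.5 Mb or 10.5%, in 31016 regions, and H3K4me3 the least, 4.08 Mb or 3.42%, in 14717 regions. H3K27me3 had 27784 regions over 10.5 Mb (8.84%), H2A.Z 30594 over 7.82 Mb (6.56%) and H3 23379 over 5.95 Mb (4.99%). Regions were short, with medians from 183 bp for H2A.Z to 330 bp for H3K4me1, and 39.2% (H3K4me1) to 63.4% (H3) of them sat at the smallest size of their library. Joining regions closer than 500 bp left 20043 regions for H3K4me1 and 17997 for H3K27me3, so the number of regions of these marks is in part a matter of how they were joined.

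The longest H3K27me3 region, of 3301 bp (chromosome 3, 6382865 to 6386165), lay at BRC1 (AT3G18550), a transcription factor gene that restrains the outgrowth of shoot branches. The region began 424 bp before the gene's start. Second was a region of 2630 bp on AT1G02190. For H3K4me1 the longest regions lay inside AT3G63340 (2272 bp) and AT4G26660 (2153 bp), beginning 1091 and 458 bp after the gene starts. H3K4me3 was longest on AT1G18460 (1479 bp) and AT1G72160 (1191 bp), and H2A.Z on AT4G38062 (1536 bp) and AT5G61200 (1409 bp). The longest H3K27ac region, 2321 bp, lay on the pseudogene AT1G10160, followed by 1737 bp over CBL1, which encodes a calcium sensor, and its neighbour AT4G17616. H3 regions were longest at the pseudogene AT4G07917 (1580 bp) and at AT4G28260 (1202 bp). Near the centromeres, within 3 Mb on either side, lay 25.2% of the genome and 24.1% of the bases covered by H3, against 8.46% for H3K4me3 and 11.7% for H3K27me3.

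The first comparison placed the regions relative to annotated genes. H3K4me1 lay inside genes: 82.6% of its regions had their midpoint in gene bodies away from both ends, where shifts gave 41.4% on average, and only 7.02% in 5' zones, where shifts gave 21.5%. H3K4me3 and H3K27ac lay at gene starts, with 46.9% and 41.2% of regions in 5' zones. H2A.Z with 36.1% and H3K27me3 with 30.0% were also enriched there, and H3 with 14.7% was depleted. Each of these 5' zone values was outside the range of all 1000 shifts.

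Away from genes, regions of every mark were scarcer than after shifting. Sequence more than 1000 bp from any gene held 0.116% of H3K4me1 regions and 0.788% of H3K4me3 regions, where shifts gave 11.0%. For H3K27ac the share was 3.03%, for H3 4.25% and for H2A.Z 4.54%. H3K27me3 came closest to its shifts, with 9.22% of regions in distal space against 11.0%. That last depletion ended when 3 Mb around each centromere were left out, with 8.74% observed and 8.00% from shifts, and with shifts of only 20 to 200 kb, which gave 9.24%.

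**Figure D1:**
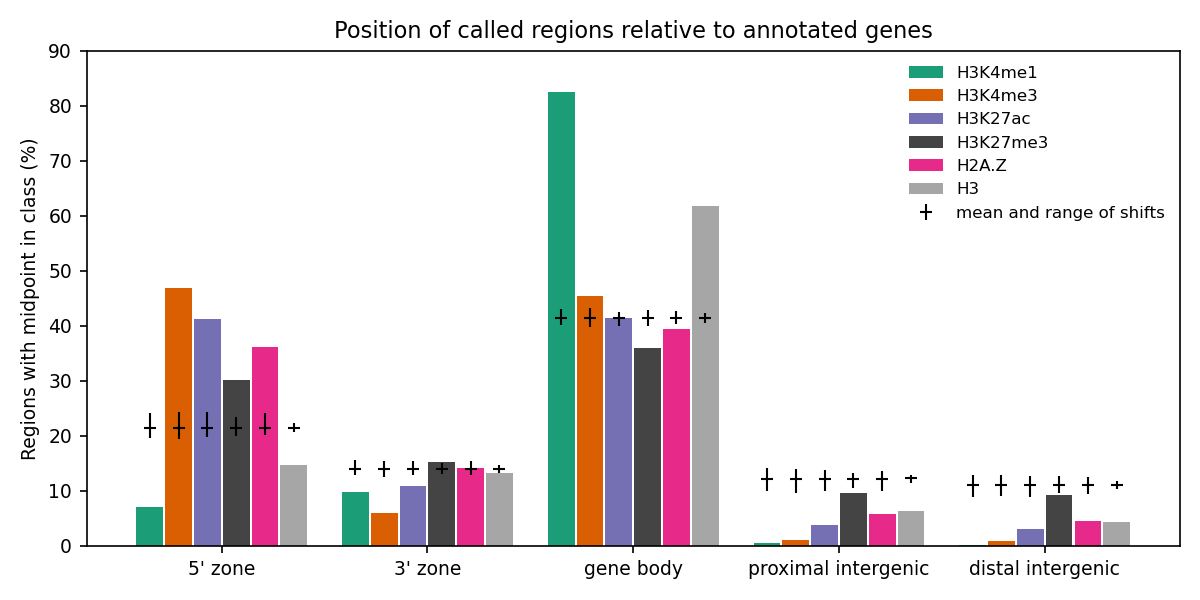
Percent of called regions whose midpoint lies in each class of sequence (vertical axis) for 5 marks and H3 (coloured bars), with the mean and full range of 1000 shifts in black. H3K4me1 reaches 82.6% in gene bodies and H3K4me3 46.9% in 5' zones, and H3K27me3 is the mark whose distal share, 9.22%, comes closest to the shifts.

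The second comparison asked on which side of a gene start each mark lay. At 9519 isolated starts, H3K4me3 covered 13.1% of bases in the 500 bp downstream and 0.648% in the 500 bp upstream, a ratio of 20.2. The ratio was 9.21 for H3K27ac (28.9% against 3.14%), 8.37 for H3K4me1 (3.02% against 0.361%), 4.38 for H2A.Z (16.9% against 3.87%) and 3.26 for H3 (4.31% against 1.32%). H3K27me3 had the smallest ratio, 1.98, since 9.79% of upstream bases were covered as well, a value inside the range of the shifts (7.91% to 9.85%). All 6 ratios lay above every shift, and they did so in windows of 250 and 1000 bp too. For H3K4me1 and H3 the downstream coverage itself lay below every shift (lowest shifts 9.55% and 4.48%), and so did the upstream coverage. Their ratios therefore reflect a stronger depletion upstream and not a gathering of regions downstream of the start. Isolated starts had no gene upstream by definition, which favours a high ratio for any mark that lies in genes.

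The marks had different positions along the gene. Coverage by H3K27ac and H2A.Z was highest in the 50 bp bin centred 375 bp after the start, at 36.7% and 20.4% of genes' bases. H3K4me3 (18.1%) and H3K27me3 (22.1%) were highest at 475 bp, and H3K4me1 only at 1225 bp, at 17.8%. Scaled to gene length, the median position of H3K4me3 regions inside genes was 20.4% of the way from start to end, followed by H3K27ac (25.5%), H2A.Z (33.3%), H3K27me3 (36.6%), H3 (49.0%) and H3K4me1 (53.4%). At 2958 divergent starts, with a second gene starting in the opposite direction within 1000 bp, the ratio of the downstream to the upstream side was 5.24 for H3K4me3, 4.68 for H3K27ac, 3.86 for H3K4me1, 2.87 for H2A.Z, 2.38 for H3 and 1.98 for H3K27me3. The upstream window of such a start can reach into the neighbouring gene's own downstream side.

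**Figure D2:**
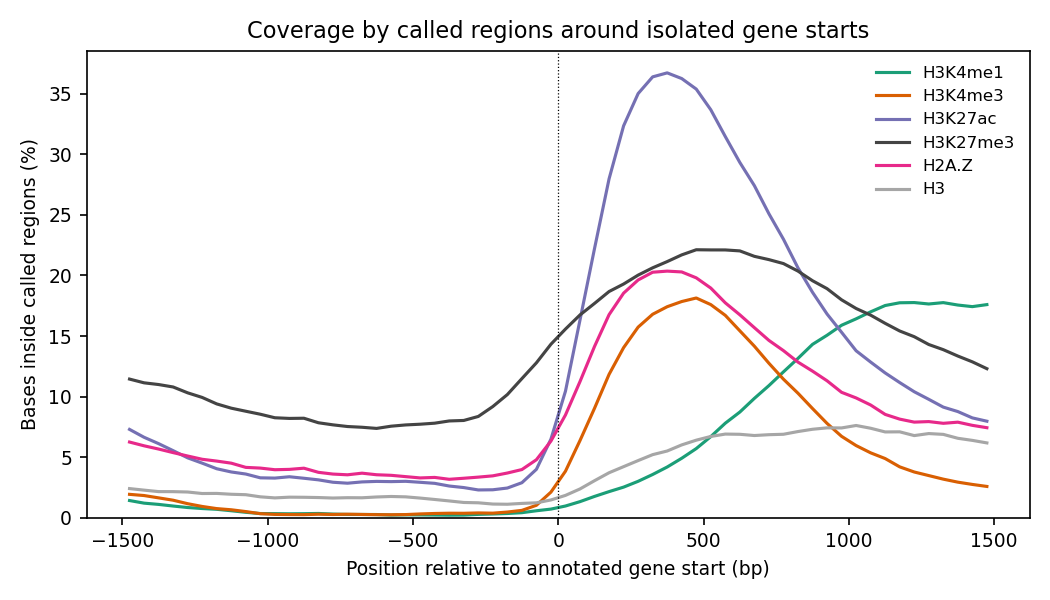
Percent of bases inside called regions (vertical axis) in 50 bp bins from 1500 bp before to 1500 bp after isolated gene starts (horizontal axis, bp), with 1 line per mark. H3K27ac peaks at 36.7% in the bin centred at 375 bp, and H3K4me1 rises later, to 17.8% at 1225 bp.

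The third comparison measured how many bases pairs of marks shared. H3K4me3 and H3K27ac shared the most relative to shifts, with a log2 ratio of 2.65: 57.1% of bases under H3K4me3 also lay under H3K27ac. H2A.Z shared bases with H3K27ac (log2 ratio 1.79), H3K4me3 (1.67), H3K27me3 (1.31) and H3K4me1 (0.87). H3K4me1 and H3K27me3 were the pair that shared fewer bases than in every shift, with a log2 ratio of -0.61. H3K4me1 and H3K27ac shared more than shifts (0.70), and H3K4me3 and H3K27me3 did as well (1.00), over 721497 bases.

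H3 regions overlapped all of the marks, with log2 ratios of 1.90 for H3K4me1, 1.54 for H2A.Z, 1.46 for H3K27ac, 1.18 for H3K4me3 and 0.61 for H3K27me3. H3K4me1 and H3K4me3 lay within the range of the shifts (0.19), and their call went either way with the method: lower (-0.35) once regions at the smallest size were left out, and higher (0.19) against random placement. Long regions of H3K27ac and H3K27me3 kept apart: the log2 ratio of 0.54 turned to -0.62, lower than every shift, when only regions of at least 500 bp were used. With that choice H3K4me1 with H3K27ac (0.32) and H3K27me3 with H3 (0.65) came to lie within the range of the shifts.

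**Figure D3:**
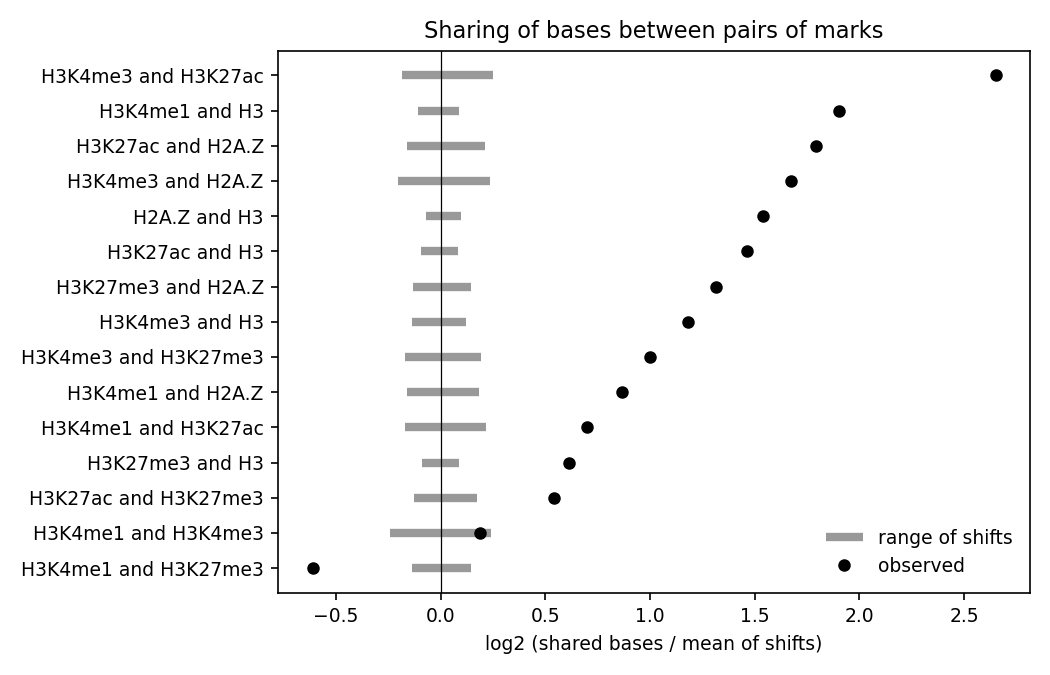
The log2 ratio of bases shared by each of 15 pairs of marks to the mean of 1000 shifts (points, horizontal axis), with the range of the shifts as grey bars. H3K4me3 with H3K27ac stands highest at 2.65, and H3K4me1 with H3K27me3 is the pair below its shifts, at -0.61.

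The fourth comparison concerned regions with the animal enhancer signature, H3K27ac with H3K4me1 and without H3K4me3. Of the 36146 H3K27ac regions, 6648 (18.4%) carried it, a number within the range of the shifts (4995 to 6680); with at least 50% of the H3K27ac region shared with H3K4me1, 5773 did, more than in every shift. They lay in genes: 71.2% had their midpoint in gene bodies and 16.0% in 5' zones. Only 13 of them, 0.196% (95% interval 0.104% to 0.334%), lay in distal intergenic space, against 1084 of the 29498 other H3K27ac regions, 3.67% (3.46% to 3.90%). The difference, -3.48 percentage points, was smaller in size than in every shift (-14.7 to -10.9). Shifts could not test this difference, since 3.03% of all H3K27ac regions were distal and shifting raised that share. Of all H3K4me1 regions 0.116% were distal, so asking for H3K4me1 by itself keeps the distal share low. Without regions at the smallest size, 2927 regions had the signature and 0% of them were distal.

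The longest of the 13, with 811 bp on chromosome 1 (14284477 to 14285287), ended 604 bp from the nearest gene, the long noncoding RNA gene AT1G07027. Next came 485 bp at a distance of 3536 bp from EDA12 (chromosome 2, 15100695 to 15101179) and 305 bp at 1595 bp from the noncoding gene AT1G07273 (chromosome 1, 16990670 to 16990974). A region of 298 bp lay 1172 bp from AT5G17560, and the fifth place was shared by regions of 275 bp near GRF11, a 14-3-3 protein gene, and AT5G04160. At EDA12 and AT5G17560 the signature rested on 31 and 55 bp of H3K4me1. The region near AT1G07273 had 287 of its 305 bp under H3, and that near AT5G17560 had 278 of its 298 bp under H3K27me3. Those near AT1G07027, AT1G07273 and GRF11 lay in the centromere flank of chromosome 1. Distal H3K27ac regions as a whole, 1097 in number, rarely touched H3K4me1 (1.19%, 95% interval 0.632% to 2.02%) or H3K4me3 (1.09%, 0.566% to 1.90%). Sharing was more frequent with H3K27me3 (18.9%), H2A.Z (17.3%) and H3 (10.7%), and 64.3% of the distal regions were of the smallest size, against 29.8% in 5' zones.

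The fifth comparison counted marked protein-coding genes. H3K27ac marked 15531 of the 27444 genes (56.6%), where shifts gave 9233 on average, and H3K4me1 marked 14301 (52.1%; shifts 9911). H3K27me3 marked 11490 genes (shifts 8860), H2A.Z 10481 (7158), H3 11689 (8949) and H3K4me3 7065 (3886). Each number lay above every shift. Marked genes were longer than unmarked ones for all 6 targets, which a rule of 200 bp favours, with medians of 2747 against 1424 bp for H3K4me1 and 2687 against 1686 bp for H3. Almost all genes with H3K4me3 also had H3K27ac (89.1%), against 45.3% of the genes without H3K4me3.

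H2A.Z was more frequent on genes with H3K27me3 and without H3K4me3 (49.5% of 8403) than on those with H3K4me3 and without H3K27me3 (37.1% of 3978), while H3K27ac was the other way round (40.2% and 89.2%). On genes with both H3K4me3 and H3K27me3 the share with H2A.Z was 34.9%, and on genes with neither it was 31.5%. Both H3K4me3 and H3K27me3 marked 3087 genes, above the shifts (2498 to 3021), but this excess depended on the count used: without regions at the smallest size, 1382 genes were fewer than in every shift (mean 1580), and without the centromere flanks the 2873 genes lay within the shifts. The most bases under both marks were found on AT5G56240 (1284 bp), AT3G21690 (946 bp), FAB1C (944 bp), SPT16 (935 bp) and TGA1 (848 bp). FAB1C encodes a phosphatidylinositol phosphate kinase, SPT16 a subunit of the histone chaperone FACT, and TGA1 a bZIP transcription factor. When at least 50% of a gene had to be covered, the order of the marks changed: H3K27me3 marked 2366 genes, H3K27ac 1242, H3K4me1 714, H2A.Z 687, H3K4me3 133 and H3 114, and H3K4me1 then lay below every shift (mean 1246).

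Regulators of epidermal cell fate differed from gene to gene in their marks, and some carried both H3K27ac and H3K27me3. Of 14 non-hair regulators, 8 carried H3K27ac, 5 H3K27me3, 8 H2A.Z and 4 H3K4me3, and the list did not stand apart from random lists for any of the 6 targets. TTG1, a WD40 protein gene needed for non-hair fate, had 1017 bp of H3K27ac and 581 bp of H3K4me3, WER, a MYB gene, had 518 bp of H3K27ac, and CPC, whose small MYB protein acts on neighbouring hair cells, had 672 bp; none of the 3 had H3K27me3. GL2, the homeodomain gene whose product suppresses hair formation in these cells, carried 1311 bp of H3K27me3 together with 412 bp of H3K27ac and 378 bp of H3K4me3. The bHLH genes GL3 and EGL3 had 241 and 311 bp of H3K27me3, GL3 also 309 bp of H3K27ac, and MYB23 had 241 bp of H3K27me3 and 179 bp of H3K27ac. TRY had no region of any target, ETC1 had 183 bp of H2A.Z, and TTG2 had 449 bp of H2A.Z and 254 bp of H3K4me1. Regions of 241 bp for H3K27me3 were of the smallest size, and none of the GL2 regions of H3K27me3 reached 500 bp. The GL2 promoter also drove the construct used to purify the nuclei.

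With the rule of 200 bp, root hair genes carried H3K27me3 more often and active marks less often than random lists. H3K27me3 marked 15 of 23 (65.2%; random lists averaged 44.4%, percentile 97.6), H3K27ac 6 (percentile 0.055), H3K4me3 2 (percentile 1.60) and H3K4me1 8 (percentile 1.93). The bHLH regulators of hair growth had 1348 bp of H3K27me3 on RHD6, 800 bp on RSL1, 398 bp on RSL2 and 1158 bp on RSL4, while LRL3 had none and 710 bp of H2A.Z. COBL9, needed for hair tip growth, had 1608 bp of H3K27me3, the proline-rich cell wall protein gene PRP3 1016 bp, and the expansin genes EXPA7 and EXPA18 482 and 381 bp. RBOHC, the NADPH oxidase gene of hair growth, had no H3K27me3 and 402 bp of H3K27ac. Without regions at the smallest size, 10 of the 23 had H3K27me3 and the list no longer stood apart (percentile 94.5), and EXPA7 lost all of its H3K27me3. With regions of at least 500 bp alone, 2 of the 23 were marked by H3K27me3, against 11.7% of all genes. With at least 1 bp covered as the rule, H3K4me3 (30.4%) and H3K4me1 (39.1%) no longer stood apart on root hair genes.

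Nearly all regulators of shoot and flower development and genes of the embryo and seed carried H3K27me3. All 23 shoot and floral regulators were marked, and 0 of 10000 random lists reached that; AG had 4670 bp, FLC 3773 bp, KNAT1 2899 bp and STM 2785 bp. Of 12 embryo and seed genes 11 were marked (percentile 99.9), led by ABI3 (2819 bp), MEA (2266 bp) and the seed storage protein gene CRU3 (1829 bp). Both lists stood apart for few members with the other marks of H3: H3K27ac was found on 5 of the 23 and 1 of the 12, H3K4me3 on 3 and 0, and H3K4me1 on 10 and 3. H2A.Z was more frequent than in random lists, on 15 of 23 (percentile 97.8) and 9 of 12 (percentile 98.9), a call that both lists lost without regions at the smallest size, as did embryo and seed genes for H3K4me1 (16.7%). With regions of at least 500 bp alone, 18 of the 23 and 11 of the 12 were still marked by H3K27me3, against 11.7% of all genes.

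Markers of other root tissues differed in their share with H3K27me3. All 9 root cap and root tip markers had H3K27me3 (percentile 99.9), with 1573 bp on PLT3, 1438 bp on BBM and 1434 bp on PLT1, and 0 of 9 had H3K4me3 (percentile 1.65), a call that ended with at least 1 bp as the rule (22.2%). Stele, xylem and phloem markers had H3K27me3 on 10 of 18, led by VND7 (2005 bp), a regulator of xylem vessel formation, PHO1 (1924 bp) and MYB46 (1727 bp), and H3K27ac on 6 of 18, fewer than in random lists (percentile 0.12). Their H3K27me3 count did not stand apart (percentile 79.8) until regions at the smallest size were left out, when the same number, 10 of 18, had a percentile of 99.4. Of 11 endodermis markers 7 had H3K27me3 (percentile 90.3), led by MYB36 (1500 bp) and CYP86A1 (981 bp).

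Housekeeping genes had H3K27ac on 13 of 14 (percentile 99.5) and H3K4me3 on 8 of 14 (percentile 99.1), with 839 bp of H3K27ac on ACT2, 774 bp on UBC9 and 696 bp on EIF4A1. With at least 1 bp covered as the rule, the H3K27ac share stayed at 92.9% and no longer stood apart. H3K27me3 was found on 6 of the 14, with 629 bp on GAPC1 and 558 bp on GAPC2, and on 3 of the 14 without regions at the smallest size. Of 13 genes of nutrient and water transport, 7 had H3K27me3 (percentile 72.4), including FRO2 (1920 bp), HAK5 (1733 bp) and NRT2.1 (1640 bp), and 8 had H3K27ac, including the proton pump gene AHA2 (1213 bp) and AMT1;1 (1004 bp); H3K4me1, on 6, was less frequent than in random lists (percentile 1.32). Photosynthesis genes had H3K27me3 on 7 of 19 (percentile 27.4), led by LHCA2 (304 bp) and LHCB2.2 (246 bp), and H3K27ac on 6, with 818 bp on LHCA1 and 791 bp on LHCA3. Without regions at the smallest size 1 of the 19 photosynthesis genes had H3K27me3, and the list then stood apart as low (percentile 0.72). Of the 60 comparisons of a list with a target, 8 stood apart as higher and 12 as lower, none of them for H3. When at least 50% of a gene had to be covered, so few genes passed that H3K27me3 on shoot and floral regulators and on embryo and seed genes were the calls that stayed, and stele markers gained one for H3K27me3 (33.3%).

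**Figure D4:**
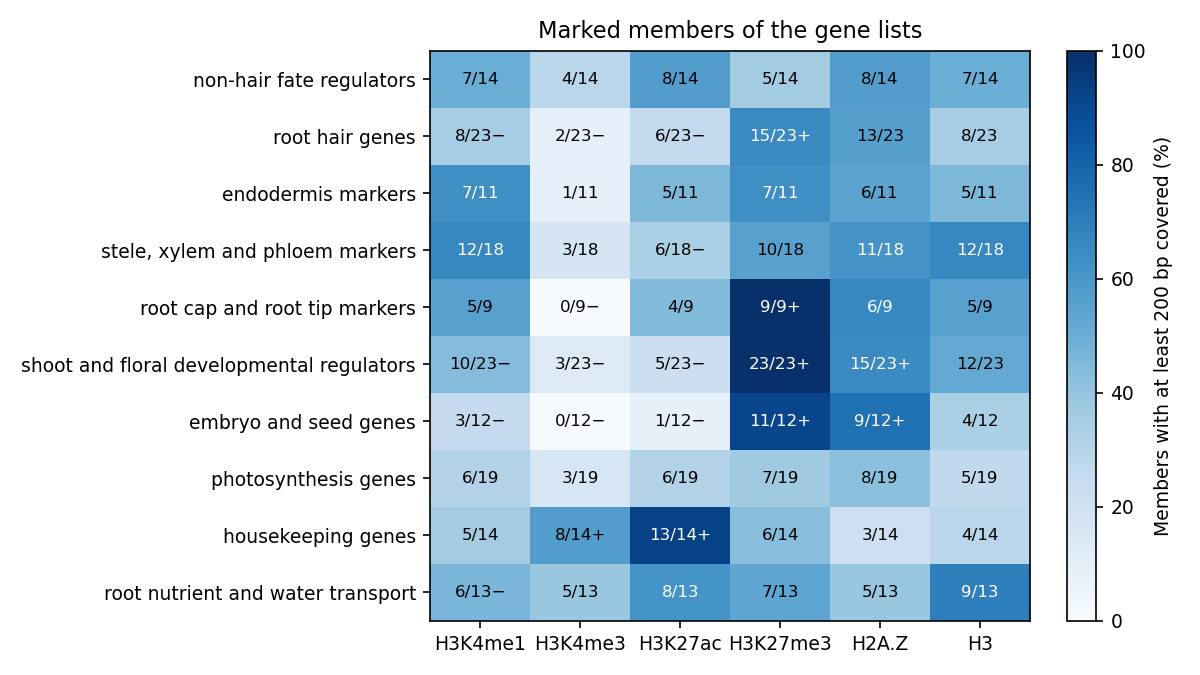
Members with at least 200 bp covered, as number and share (colour, percent), for 10 gene lists (rows) and 6 targets (columns). Plus and minus signs mark lists whose percentile among 10000 length-matched random lists, with ties split evenly, lay in the outer 2.5%. All 23 shoot and floral regulators carry H3K27me3, and 13 of 14 housekeeping genes carry H3K27ac.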

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

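Shifts of 20 to 200 kb and the exclusion of regions at the smallest size were chosen after seeing the data; the other alternatives were not. Of 378 recomputed values for 74 results, 308 kept their direction and call or, for counts, stayed within 1.5 times. Depth was unknown, so its effect could not be measured, and no library could be left out, with 1 per mark. No cause was tested for any of the changes, except where the alternative's construction gives it. Ratios at gene starts and enrichments in 5' zones kept their direction and call under every alternative run.

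With only regions of at least 500 bp, marked genes fell to 5043 for H3K4me1, 1137 for H3K4me3, 4009 for H3K27ac, 3214 for H3K27me3, 1224 for H2A.Z and 271 for H3, fewer regions being used. Genes with both H3K4me3 and H3K27me3 numbered 93, below the shifts. The log2 ratio of shared bases turned to -0.62 for H3K27ac with H3K27me3 and lost its call for H3K4me1 with H3K27ac (0.32) and H3K27me3 with H3 (0.65). The enhancer signature was left on 321 regions, 0% of them distal.

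Leaving out regions mostly inside H3 regions gave log2 ratios with H3 of -0.70 for H2A.Z, -0.63 for H3K4me3, -0.51 for H3K27ac and -0.39 for H3K27me3, which the exclusion itself produces; H3K4me1 with H3 stayed above every shift, at 0.57. The signature then held for 4238 regions, and the distal share of H3K27me3, 9.50%, lay within its shifts. Without the centromere flanks that share was 8.74%, above the mean of its shifts and within their range, and 0.0815% of signature regions were distal. With shifts of 20 to 200 kb the distal share of H3K27me3, 9.22%, was within range. Random placement gave H3K4me1 with H3K4me3 a call as higher (0.19). Joining regions closer than 500 bp gave 20043 for H3K4me1 and 17997 for H3K27me3.

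With 1 bp as the rule for a marked gene, H3K4me3 marked 11002 genes, and 4898 had both H3K4me3 and H3K27me3, within the shifts. Calls were lost for housekeeping genes with H3K27ac (92.9%), root cap and root tip markers with H3K4me3 (22.2%) and root hair genes with H3K4me1 (39.1%) and H3K4me3 (30.4%). With at least 50% of the gene covered, marked genes numbered 714 for H3K4me1, 133 for H3K4me3, 1242 for H3K27ac, 2366 for H3K27me3, 687 for H2A.Z and 114 for H3, with 18 for H3K4me3 and H3K27me3 together. So few genes passed that 0% of members were left, without a call, in shoot and floral regulators and embryo and seed genes for H2A.Z, H3K27ac, H3K4me1 and H3K4me3, in housekeeping genes for H3K27ac and H3K4me3, in root hair genes for H3K27ac, H3K4me1 and H3K4me3, in root cap and root tip markers for H3K4me3, in transport genes for H3K4me1, and in stele markers for H3K27ac. H3K27me3 lost its call on root cap and root tip markers (22.2%) and root hair genes (17.4%) and gained one on stele markers (33.3%).

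Without regions at the smallest size, 5428 genes were marked by H3 and 7128 by H3K27me3, 1382 genes had both H3K4me3 and H3K27me3, and the signature held for 2927 regions, 0% of them distal. H3K4me1 with H3K4me3 turned to -0.35, below the shifts. Calls ended for embryo and seed genes with H2A.Z (50.0%) and H3K4me1 (16.7%), root cap and root tip markers with H3K4me3 (0%), root hair genes with H3K27me3 (43.5%) and H3K4me3 (8.70%) and shoot and floral regulators with H2A.Z (47.8%), and began for H3K27me3 on photosynthesis genes (5.26%) and stele markers (55.6%). The signature's number gained a call as higher than its shifts when 50% of the H3K27ac region had to be shared (5773 regions).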

Other observations

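The tests of distal H3K27ac regions given here, the exclusion of regions at the smallest size, the gene classes and the gene families were chosen after seeing the data. Genes for small nucleolar RNAs, which guide the modification of ribosomal RNA, lay under H3K27ac, H3K4me3 and H2A.Z more often than after shifting: of 287, 43.9% had at least 50% of their length under H3K27ac, 4.90 times the mean of the shifts, 14.3% under H3K4me3 (4.40 times) and 16.7% under H2A.Z (2.53 times), each above every shift. The 625 tRNA genes lay under none of the targets as often as in any shift, with 1.28% under H3K27ac and 0.160% under H3. Transcribed pseudogenes, 926 in number, were covered by H3K27me3 (10.5%, 1.63 times) and H2A.Z (5.72%, 1.90 times) above every shift. H3 covered 43 of the 3917 other pseudogenes (1.66 times), against 42 in the highest shift, so this call was narrow.

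Families sharing a symbol stem, 80 with at least 15 members, were compared with 10000 random lists matched on gene length, for H3K27me3 and H3K4me3. H3K27me3 marked 85 of 115 MYB genes, 46 of 67 WRKY genes, both of them transcription factor families, and 31 of 42 UMAMIT genes, which encode amino acid exporters, more than any random list. Of 160 EMB genes, named for mutants arrested as embryos, 39 had H3K27me3, fewer than any random list. H3K4me3 was found on 3 of 40 BGLU genes and 2 of 42 UMAMIT genes, fewer than any random list. These families were picked from 160 comparisons by their values.

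H3K4me3 and H3K27me3, marks of opposite gene activity, shared more bases than shifts although nuclei of 1 cell type had been purified. Both gather near gene starts. From 500 bp before to 1000 bp after starts, reassigning H3K27me3 profiles among genes of similar length left a log2 ratio of 0.30. There, 654728 bases were shared, against at most 559214 after reassignment. Annotated starts and gene length alone therefore did not give all of the sharing in these windows. Reassignment did not keep a profile's place along the chromosome, which could raise the ratio too. The 0.30 and the log2 ratio of 1.00 to shifts rest on different bases and references, so the part of 1.00 due to gene starts was not measured. Against shifts, leaving out regions mostly inside H3 regions gave 0.99, and leaving out regions of the smallest size gave 0.98, both above every shift. These values argue against regions mostly inside called H3 regions, and against the smallest calls, as the source of the whole ratio of 1.00. Regions only partly inside H3 regions were kept, and background too weak to be called for H3 would remain, so such background stays open. The 0.30 in windows at gene starts was not recomputed without those regions, so for that value both explanations stay open. The smallest calls also stay open for the count of genes with both marks. That count turned from above the shifts (3087) to below them without the smallest regions (1382) and with regions of at least 500 bp (93). Whether both marks sat on the same nuclei, on different copies of a gene or came from nuclei of other cells carried along in the purification was not tested and stays open, and so does the separate input of H3K27me3.

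Relative to shifts, H3K4me1 and H3 shared more bases than any pair other than H3K4me3 with H3K27ac. Both lie in gene bodies, but inside genes, at least 500 bp from either end, 200 bp bins still gave a log2 ratio of 1.16 to independence, from 1.12 to 1.19 over the 5 chromosomes. GC content removed little of it: within classes of equal GC the log2 ratio was 1.104. These values argue against gene position and GC content as the whole cause; a difference in how well fragments from such places map or shear was not tested and may remain, and no biological explanation was tested.

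Distal H3K27ac regions mostly lacked H3K4me1 (1084 of 1097), and the shares that follow are of all 1097. They could be starts of genes missing from the annotation. Of them 1.09% touched H3K4me3 (upper bound 1.90%), against 39.0% of H3K27ac regions in 5' zones. The low share bears only on starts that carry H3K4me3, which marked 25.7% of annotated protein-coding genes. Distal regions were also shorter (median 179 bp against 277 bp), and the comparison was not matched on length. Unannotated starts without H3K4me3 therefore stay open. Background shared with H3 stays open for a part: 10.7% touched H3, above random placements in distal space (at most 5.10%), and the rest did not touch it. Calls at random positions would meet H2A.Z as rarely as random placements in distal space, 4.55% on average and at most 6.93%, and 17.3% did; outside the centromere flanks it was 17.2% against at most 9.87%. Shared background could raise that value too, and a share of false calls is not excluded, since 64.3% of these regions were of the smallest size; no biological explanation was tested.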
